A study of Homo sapiens with 12 samples.

How the data were processed

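The libraries were polyadenylated, strand-specific RNA sequencing of SUM159 tumour cells grown in immunodeficient mice that were 8 weeks old at injection, and sorted after staining for human CD24 and CD44. According to the submitters' processing notes, reads were aligned with STAR to hg38, and the version of STAR and the annotation release were not given in the sources used here. The deposited values were raw gene counts per library for 26475 gene symbols, with 1 column for reads of either strand and 1 for each strand, and the column for the reverse strand (column 4), the strand this library kit reads, was used. Reads on the opposite strand made 1.59% to 1.75% of both strands. No mitochondrially encoded gene and no line for unassigned reads was among the deposited counts. Whether reads of the mouse host were removed before alignment was not given in the sources used here. Gene positions came from RefSeq on GRCh38.p14, which shares its primary assembly with hg38, and 23749 of the 26475 symbols matched it.

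Totals ran from 17736610 to 47587142 counts, with the 3 CD24-low libraries of the fasting-mimicking diet at most 18579816 and every other library at least 29049144. The 10 most abundant genes held 6.94% to 10.9% of a library. Between replicates, the median variance of a gene was 5.61 to 17.8 times counting noise, so that spread between samples, not counting, set the precision of most values. The p-values measure that spread between samples. Counting intervals are exact and cover counting error only, as do floors, which rest on 3 counts over a group. A fitted fold change of a gene with under 4 counts in its lower group depends on the prior count and is no bound. The standard error printed with such a fold change depends on the prior count too and is no measure of its precision.

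Each group of 3 was a population within a diet, and the 4 groups were fitted together with edgeR 4.0.16 (quasi-likelihood, robust, TMM scaling, default count filter by group, R 4.3.3), with 8 residual degrees of freedom and a biological coefficient of variation of 0.19. The filter kept 15461 genes and left out 11014. The 6 contrasts were the populations within each diet and averaged over both, the diets within each population, and the interaction. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested, without a minimum fold. Where no tool is named, a gene's adjusted p is that of edgeR and a list's that of camera.

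Gene lists for pathways, cell types and RNA quality, 52 in number, were written down before the data were examined. The 49 with at least 5 measured members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with its preset correlation between genes of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation was an alternative, and fry, which tests each list by itself, was run beside it. Between diets fry called 17 lists in CD24-low cells, 12 of them shared with the 17 of camera, and 1 of the 16 in CD24-high cells, fatty acid oxidation. Between populations it called 0 against 7 under the control diet, 10 against 16 with 7 shared under the fasting-mimicking diet, and 6 against 14 with 6 shared over both. For the interaction it called 4 against 11, with 3 shared. Libraries of the groups compared overlapped in the mean log2 CPM of a called list in 7 of 7 lists between populations under the control diet and 5 of 16 under the fasting-mimicking diet, and between diets in 2 of 17 in CD24-low and 8 of 16 in CD24-high cells. A list's members were counted as rising or falling over all genes tested, and again adjusted over the list alone. One of the 49 held genes chosen by recall of the study, of which 12 were measured, and it was adjusted with the others.

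Genes were named by a rule. In each contrast it took CD24 and CD44, and up to 6 genes each with the largest and the smallest log2 fold change among genes called, with a mean of at least 2 CPM in the higher group and no overlap between the libraries compared, a condition not set for the interaction. Unnamed loci and non-coding symbols were left out. Where no gene was called it took the 3 smallest p in each direction, as values. It also took up to 3 members with the smallest p of each list called and the genes chosen by recall of the study. The text prints part of these genes and, outside the interaction, leaves out most of those whose call was lost without a single library. Some genes that the rule took are withheld and not reported.

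Alternatives were reads of either strand, RLE scaling, no count filter, DESeq2 1.42.0, only the libraries of the groups compared (4 residual degrees of freedom), a block for replicate number, and each of the 12 libraries left out. Thinning every library to the smallest total was added after the data had been seen. Of the fits without a library, the text prints every adjusted p of 0.05 or more of a call it names, or the number of fits that kept the call and the highest value, and the others lay below 0.05. The labels give replicate numbers but not what they share. Deviations from group means of libraries with the same number correlated between CD24-low and CD24-high cells of the fasting-mimicking diet at 0.444, 0.285 and 0.485, all above the 0.1 set for a pairing, so the numbers were taken to pair these. The main fit did not use this pairing, and results with the block are given beside it as an alternative. Under the control diet the values were 0.445, 0.522 and 0.0373, and across diets they ran from -0.221 to 0.0824. By the 0.1 set, the numbers were not taken to pair those. Each control value still lay above the highest value with another number (0.171, -0.195 and -0.00931), so a pairing under the control diet was not excluded. The block for comparisons of populations and for the interaction still used the number within both diets. For comparisons of diets it used the number alone.

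The pipeline was tested on simulated data in which 100 genes changed by 2-fold and 100 by 4-fold. Of the 15236 genes tested there, 173 were called, 73% of the 2-fold and 92% of the 4-fold changes were recovered and 8 calls were false. A contrast simulated without change gave 0 calls, and of 50 simulated lists the planted one and no other was called. Genes were simulated independently of each other, so this does not test list calls where genes are correlated. Principal components used log2 CPM of the genes tested, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Alignment, sequence reads and a mouse reference were not used here.

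Some rules for judging the explanations were set after their values had been seen. They are a minimum of 5 lymphoid markers for comparing lineages, leaving dilution open where scaling centres the median of all genes, and the rule for an equal diet difference in both populations, which excludes it where more than 5% of the genes have a called interaction. An earlier form of that last rule compared quartiles of the change in the 2 populations and excluded an equal difference for the higher and the lower genes alike. It was dropped because the genes were chosen for their change in CD24-low cells, so a smaller change in CD24-high cells was partly built in.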

Results

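Messenger RNA was sequenced from tumours that SUM159 cells, an established human line of triple-negative breast cancer, formed in female immunodeficient mice. The mice ate a standard diet or went through cycles of a fasting-mimicking diet on 4 days of each week. Tumour cells stained with antibodies to human CD44 and CD24 were sorted into CD44-positive cells with little CD24 (CD24-low), taken as enriched for cancer stem cells, and cells with much CD24 (CD24-high), taken as more differentiated. The 12 libraries formed 4 groups of 3: control diet CD24-low (CTR_LO), control diet CD24-high (CTR_HI), fasting-mimicking diet CD24-low (FMD_LO) and fasting-mimicking diet CD24-high (FMD_HI). Counted reads were 47587142, 29820825 and 32473413 in CTR_LO and 32843175, 29049144 and 32916552 in CTR_HI. FMD_LO had 17736610, 18228815 and 18579816 and FMD_HI 31903233, 33911930 and 37779053. Of the genes in the files, 15461 had enough counts to be tested. Values below are CPM, counts scaled to the size of the library, as mean ± SD with n = 3 per group, or log2 fold changes ± standard error. That standard error is approximate: the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Positions are on GRCh38.

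The FMD_LO libraries stood apart from the other 9. The first principal component held 57.4% of the variance and placed FMD_LO at 86.1, 88.9 and 79.5, CTR_LO replicate 2 at 2.35 and the remaining 8 libraries between -46.1 and -24.3. The messenger RNA of the sort antigens did not separate the groups. CD24 (chromosome 6, 106969831 to 106976855) stood at 2.15 ± 0.77 CPM in CTR_LO, 1.90 ± 0.827 in CTR_HI, 1.59 ± 0.481 in FMD_LO and 2.11 ± 1.01 in FMD_HI. CD44 (chromosome 11, 35139171 to 35232402) stood at 930 ± 151, 992 ± 188, 747 ± 137 and 1080 ± 165 CPM. With all libraries, the count filter and no block neither gene passed in any comparison with edgeR, and the smallest adjusted p was 0.507 for CD24 and 0.0775 for CD44. CD44, compared between populations under the fasting-mimicking diet, passed with a block by number (adjusted p = 0.0116), without FMD_LO replicate 1 (0.0379) and without the count filter. Averaged over both diets it passed with the block (0.0411).

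**Figure D1:**
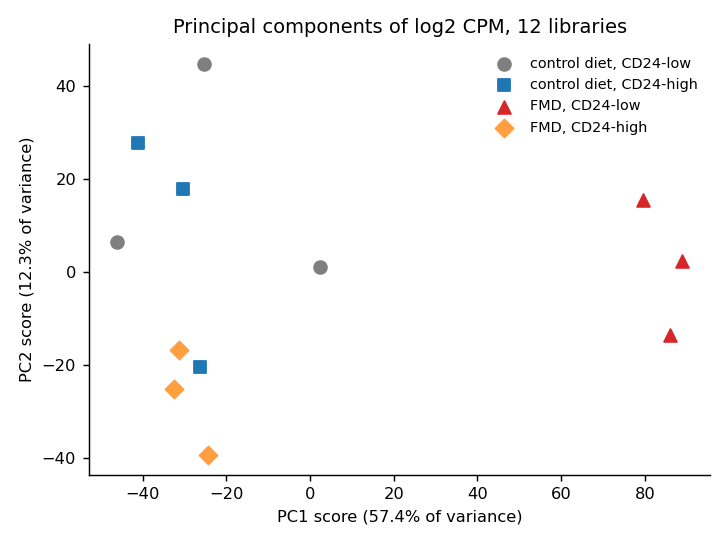
Principal components of log2 CPM of the genes tested, 1 point per library. The 3 CD24-low libraries of the fasting-mimicking diet lay apart on the component that held 57.4% of the variance.

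The comparison of diets within CD24-low cells asked what the fasting-mimicking diet changed in the stem-like population. Reads of mouse host cells were not separated from those of tumour cells, so neither higher nor lower values need be changes in tumour cells. By camera with its preset correlation, matrix and mesenchymal genes lay higher as groups in FMD_LO than in CTR_LO, among them THBS1, a matrix glycoprotein that activates latent TGF-beta, and LOX, a collagen cross-linking enzyme. Hypoxia-response, PI3K and protein kinase A lists and markers of white blood cells and fibroblasts lay higher too, while mitotic, cholesterol-synthesis, epithelial and ribosomal protein lists lay lower. None of the 17 lists called kept its call with an estimated correlation, where the smallest adjusted p was 0.41. Of 15461 genes, 2533 differed at an adjusted p below 0.05, 1863 of them higher in FMD_LO and 670 lower, and the median log2 fold change was 1.20 among the higher and -0.638 among the lower. These differences were 3 libraries against 3: without CTR_LO replicate 3 the count was 1577, without FMD_LO replicate 1 it was 1662 and without FMD_LO replicate 2 it was 1562. The lower genes numbered 335 without CTR_LO replicate 1, 261 without CTR_LO replicate 3, 284 without FMD_LO replicate 1 and 212 without FMD_LO replicate 2.

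Leukocyte genes were among the largest rises. PTPRC, which encodes the leukocyte antigen CD45 (chromosome 1, 198638713 to 198757476), rose from 2.94 ± 0.369 to 51.3 ± 7.78 CPM (log2 fold change 4.12 ± 0.27, adjusted p = 1.17e-06). SPI1, the transcription factor PU.1 of myeloid cells (chromosome 11, 47354860 to 47378547), rose from 1.38 ± 0.647 to 43.6 ± 3.87 CPM (5.02 ± 0.41, adjusted p = 1.33e-05). CSF1R, the receptor of the macrophage growth factor CSF1 (chromosome 5, 150053295 to 150113365), rose from 1.5 ± 0.278 to 25.2 ± 5.04 CPM (4.08 ± 0.31, adjusted p = 3.15e-06). The neutrophil collagenase MMP8 (chromosome 11, 102711796 to 102724954) rose from 0.0474 ± 0.0507 to 7.86 ± 2.66 CPM (7.32 ± 0.71, adjusted p = 2.26e-05). FPR2, a receptor of phagocytes (chromosome 19, 51761180 to 51770531), rose from 0.0685 ± 0.0573 to 7.90 ± 1.18 CPM (6.87 ± 0.53, adjusted p = 3.72e-06). The leukocyte tetraspanin gene CD37 had 1 count in CTR_LO and 309 in FMD_LO, a ratio of 660 with a counting interval of 118 to 26200. Of 13 myeloid markers measured, 6 rose and none fell, 7 rose when adjusted over the list alone, the median was 2.12 and the list rose against all other genes (camera, adjusted p = 1.37e-05), with adjusted p = 0.41 with an estimated correlation. Only 4 of the 13 reached 10 CPM in the control libraries, and 1 is also in another list.

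Fibroblast and vessel marker lists lay higher too. Of 15 fibroblast markers, 8 rose and none fell, and 9 rose when adjusted over the list alone. The median was 1.19 (adjusted p = 3.61e-04, adjusted p = 0.617 with an estimated correlation). THBS2, a matrix glycoprotein of stromal cells (chromosome 6, 169215785 to 169253846), rose from 19.3 ± 9.23 to 143 ± 20.2 CPM (2.89 ± 0.32, adjusted p = 1.05e-04). COL1A2, a chain of type I collagen (chromosome 7, 94394895 to 94431227), rose from 2660 ± 1380 to 9730 ± 2510 CPM (1.87 ± 0.41, adjusted p = 0.00985). In the control libraries 11 of the 15 reached 10 CPM, and 7 are also in another list. Of 13 endothelial markers, 3 rose, TEK among them, and 6 rose when adjusted over the list alone, with a median of 0.62 (adjusted p = 0.0335, adjusted p = 0.617 with an estimated correlation). That list's adjusted p was 0.0509 without FMD_LO replicate 1, 0.0985 without FMD_LO replicate 3 and 0.0648 with libraries thinned to equal depth. TEK, an angiopoietin receptor (chromosome 9, 27109225 to 27230174), rose from 0.664 ± 0.806 to 4.85 ± 1.90 CPM (2.91 ± 0.69, adjusted p = 0.0122), though with only the compared groups in the fit its adjusted p was 0.0723. Of the 13, 2 reached 10 CPM in the control libraries and 1 is also in another list.

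**Figure D2:**
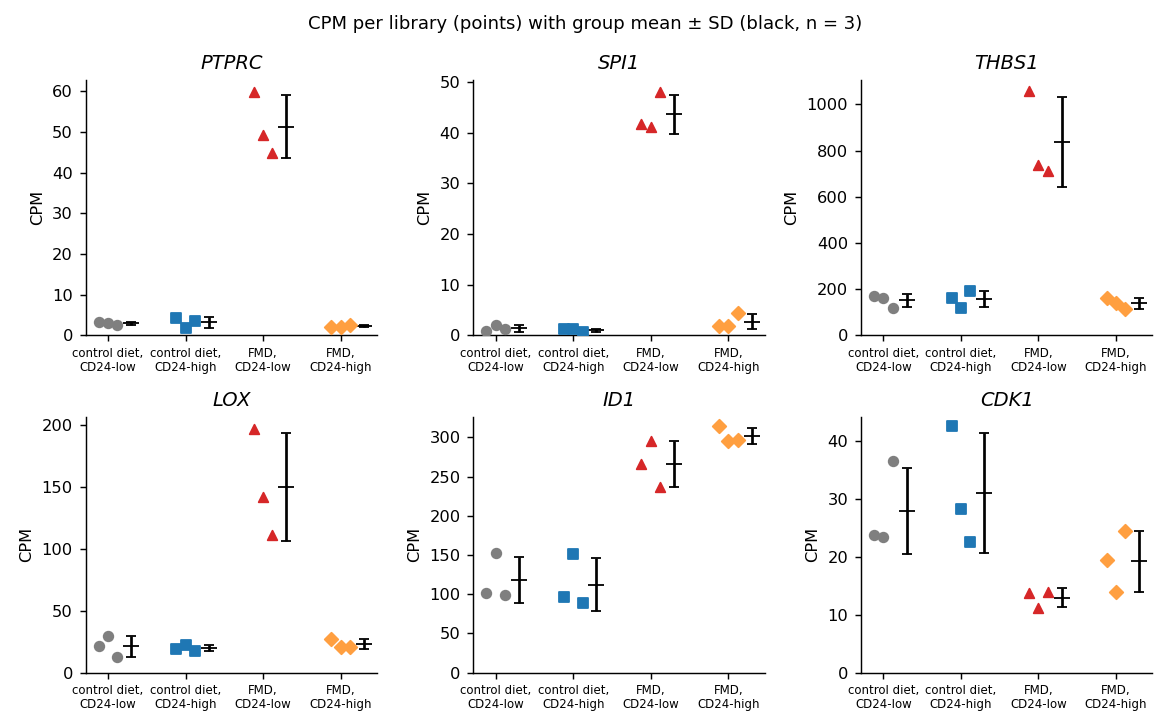
CPM in each library of the leukocyte genes PTPRC and SPI1, the matrix genes THBS1 and LOX, ID1 and the mitotic kinase gene CDK1. Bars are mean ± SD with n = 3.

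Matrix and mesenchymal lists lay higher in the same libraries, with fewer than 1 in 2 members passing. Of 35 mesenchymal genes, 14 rose and none fell, and 15 rose when adjusted over the list alone. The median was 0.53 (adjusted p = 9.07e-06, adjusted p = 0.658 with an estimated correlation). LOX (chromosome 5, 122063195 to 122078259) rose from 21.2 ± 8.44 to 150 ± 43.6 CPM (2.83 ± 0.29, adjusted p = 6.13e-05). ZEB2, a repressor of epithelial genes (chromosome 2, 144384081 to 144520119), rose from 63.1 ± 24.7 to 305 ± 65.9 CPM (2.27 ± 0.28, adjusted p = 2.06e-04). MMP2, a gelatinase (chromosome 16, 55478830 to 55506691), rose from 784 ± 109 to 1280 ± 35.2 CPM (0.71 ± 0.12, adjusted p = 0.00124). Of 36 genes of the extracellular matrix and its remodelling, 11 rose and 2 fell, and 14 rose and 3 fell when adjusted over the list alone. The median was 0.53 (adjusted p = 8.71e-04, adjusted p = 0.658 with an estimated correlation). Of 25 TGF-beta targets, 9 rose and none fell, and 11 rose when adjusted over the list alone. The median was 0.44 (adjusted p = 7.88e-04, adjusted p = 0.658 with an estimated correlation). THBS1 (chromosome 15, 39581079 to 39599466) rose from 151 ± 27.5 to 836 ± 195 CPM (2.47 ± 0.22, adjusted p = 1.46e-05). ID1, an inhibitor of differentiation factors (chromosome 20, 31605289 to 31606510), rose from 118 ± 29.8 to 266 ± 29.0 CPM (1.18 ± 0.21, adjusted p = 0.00163).

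Hypoxia and signalling lists lay higher by camera, though most of their members did not pass. Whether these rises came from tumour cells or from host reads was not separated. Of 25 hypoxia-response genes, 8 rose and none fell, and 10 rose when adjusted over the list alone. The median was 0.53 (adjusted p = 3.61e-04, adjusted p = 0.658 with an estimated correlation). PLIN2, a coat protein of lipid droplets (chromosome 9, 19108388 to 19127492), rose from 1.01 ± 1.02 to 83.2 ± 21.6 CPM (6.44 ± 0.64, adjusted p = 1.04e-04). KDM3A, a histone demethylase (chromosome 2, 86437044 to 86492716), rose from 66.3 ± 14.0 to 165 ± 9.87 CPM (1.32 ± 0.17, adjusted p = 1.83e-04). Of 32 PI3K, AKT and mTOR components, 8 rose and none fell, and 12 rose and 1 fell when adjusted over the list alone. The median was 0.30 (adjusted p = 0.00779, adjusted p = 0.41 with an estimated correlation). RRAGA, a GTPase that recruits mTORC1 to lysosomes (chromosome 9, 19049427 to 19051025), rose from 23.3 ± 1.62 to 49.3 ± 7.2 CPM (1.08 ± 0.17, adjusted p = 7.62e-04). Of 30 protein kinase A subunits and regulators, 8 rose and none fell, and 8 rose when adjusted over the list alone. The median was 0.27 (adjusted p = 0.0178, adjusted p = 0.658 with an estimated correlation), with adjusted p = 0.0561 without FMD_LO replicate 1. PDE4B, which degrades cyclic AMP (chromosome 1, 65792510 to 66374579), rose from 11.6 ± 4.06 to 71.8 ± 9.12 CPM (2.63 ± 0.25, adjusted p = 2.44e-05). CRTC2, a coactivator of CREB (chromosome 1, 153947675 to 153958612), rose from 43.4 ± 4.46 to 126 ± 15.3 CPM (1.54 ± 0.15, adjusted p = 1.82e-05). Of 34 lysosome and autophagy genes, 7 rose and none fell, and 7 rose when adjusted over the list alone. The median was 0.15 (adjusted p = 0.0316, adjusted p = 0.658 with an estimated correlation). The lysosome list's adjusted p was 0.113 without CTR_LO replicate 2, 0.0986 without FMD_LO replicate 1 and 0.0838 without FMD_LO replicate 2.

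Mitotic and growth lists lay lower by camera, though most of their members did not pass. All 33 genes of the G2 and M phases had a negative log2 fold change, 6 fell, and 20 fell when adjusted over the list alone. The median was -0.764 (adjusted p = 2.51e-07, adjusted p = 0.658 with an estimated correlation). The mitotic kinase CDK1 (chromosome 10, 60778331 to 60794852) fell from 27.9 ± 7.46 to 13 ± 1.64 CPM (-1.10 ± 0.27, adjusted p = 0.0142), with adjusted p = 0.0703 without CTR_LO replicate 3, 0.0503 without FMD_LO replicate 1 and 0.0774 without FMD_LO replicate 2. All 30 genes of the G1 and S phases were negative and none passed over all genes or adjusted over the list alone. The median was -0.38 (adjusted p = 3.61e-04, adjusted p = 0.671 with an estimated correlation). Of 24 cholesterol-synthesis genes, 7 fell and none rose, and 10 fell when adjusted over the list alone. The median was -0.424 (adjusted p = 1.91e-04, adjusted p = 0.617 with an estimated correlation). SC5D, a late enzyme of that pathway (chromosome 11, 121292771 to 121313410), fell from 40.8 ± 3.38 to 25.6 ± 2.17 CPM (-0.67 ± 0.13, adjusted p = 0.00249). Of 47 ribosomal protein genes, 45 were negative, 4 fell, and 1 fell when adjusted over the list alone. The median was -0.275 (adjusted p = 2.56e-06, adjusted p = 0.671 with an estimated correlation). RPS15A (chromosome 16, 18781295 to 18790334) fell from 1030 ± 89.6 to 717 ± 9.49 CPM (-0.52 ± 0.12, adjusted p = 0.00814).

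Of 40 nuclear genes of oxidative phosphorylation, 1 fell and none passed when adjusted over the list alone. The median was -0.25 (adjusted p = 0.00266, adjusted p = 0.742 with an estimated correlation), with adjusted p = 0.0509 without FMD_LO replicate 1. Of 31 MYC targets, 1 fell and none passed when adjusted over the list alone. The median was -0.156 (adjusted p = 0.0412, adjusted p = 0.658 with an estimated correlation). The MYC list's adjusted p was 0.115 without CTR_LO replicate 2, 0.149 without CTR_LO replicate 3, 0.0838 without FMD_LO replicate 2, 0.0717 without FMD_LO replicate 3 and 0.0626 with libraries thinned to equal depth.

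Of 30 epithelial genes, 10 fell and 2 rose, and 13 fell and 2 rose when adjusted over the list alone. The median was -0.461 (adjusted p = 0.00416, adjusted p = 0.617 with an estimated correlation). DSP, the desmosome protein desmoplakin (chromosome 6, 7541671 to 7586714), fell from 310 ± 31.8 to 174 ± 18.5 CPM (-0.84 ± 0.15, adjusted p = 0.00215). SPINT2, a protease inhibitor of epithelia (chromosome 19, 38264573 to 38292615), fell from 33.9 ± 6.67 to 14.1 ± 2.58 CPM (-1.26 ± 0.24, adjusted p = 0.00336). Outside the lists, CAMK2B, a calcium-dependent kinase (chromosome 7, 44217154 to 44326013), fell from 25.4 ± 11.7 to 6.13 ± 1.86 CPM (-2.05 ± 0.32, adjusted p = 0.00109). TP53AIP1, a mitochondrial target of p53 (chromosome 11, 128934731 to 128942871), fell from 6.14 ± 1.23 to 1.54 ± 0.368 CPM (-1.99 ± 0.25, adjusted p = 1.55e-04). RASSF6, a RAS-association protein (chromosome 4, 73571550 to 73620631), fell from 10.3 ± 2.07 to 2.66 ± 0.0637 CPM (-1.95 ± 0.27, adjusted p = 3.35e-04).

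Genes of glucose and protein kinase A signalling chosen from what is known of the study were followed as 1 of the 49 lists, which is therefore no independent evidence of direction. Of the 12 measured, 3 rose (IGF1R, SLC2A1 and CREB1), 3 rose when adjusted over the list alone, and the list itself was not called (median 0.223, camera adjusted p = 0.201). IGF1R, the receptor of insulin-like growth factor 1 (chromosome 15, 98648539 to 98964530), rose from 67.0 ± 8.56 to 180 ± 42.7 CPM (1.43 ± 0.19, adjusted p = 1.94e-04). SLC2A1, the glucose transporter GLUT1, stood at 290 ± 82.1 in CTR_LO and 479 ± 69.2 CPM in FMD_LO (0.73 ± 0.22, adjusted p = 0.0408), and kept its call in 4 of 12 fits without one library, with adjusted p up to 0.142 without FMD_LO replicate 1 and 0.0583 with only the compared groups in the fit. CREB1, the transcription factor that protein kinase A activates, stood at 34.7 ± 3.09 and 44.4 ± 3.28 CPM (0.36 ± 0.11, adjusted p = 0.045) and kept its call in 6 of 12 such fits, with adjusted p up to 0.152 without CTR_LO replicate 3, and 0.072 with only the compared groups and 0.0993 without the count filter. The log2 fold change was 0.02 ± 0.11 for PRKACA, 0.18 ± 0.21 for PRKACB, -0.32 ± 0.33 for KLF5 and 0.07 ± 0.10 for EHMT2, with adjusted p from 0.549 to 0.942.

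**Figure D3:**
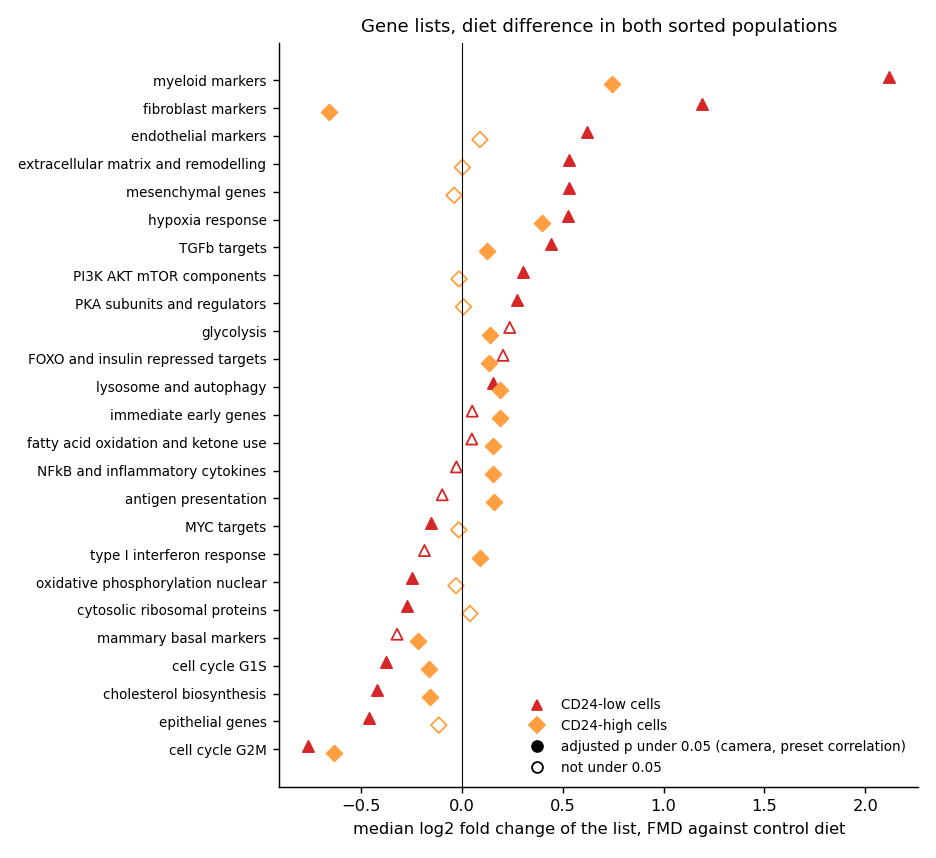
Median log2 fold change between diets of each gene list in CD24-low cells (triangles) and CD24-high cells (diamonds). Filled symbols mark an adjusted p below 0.05 in camera with its preset correlation.

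The same comparison in CD24-high cells asked what the diet changed in the more differentiated population. No gene passed in FMD_HI against CTR_HI. By camera with its preset correlation, mitotic and cholesterol-synthesis genes lay lower as groups, and genes of fatty acid oxidation, hypoxia, lysosomes and immediate early signalling lay higher. With an estimated correlation only fatty acid oxidation kept its call (adjusted p = 0.0382), and the others named had 0.571, or 0.204 for lysosomes. ID1 (chromosome 20, 31605289 to 31606510) stood at 112 ± 33.9 CPM in CTR_HI and 302 ± 10.5 in FMD_HI (1.43 ± 0.21), the smallest adjusted p of the comparison at 0.142, and its alternatives gave 2.48e-07 to 0.644. NNMT, an enzyme of nicotinamide clearance (chromosome 11, 114257806 to 114313536), stood at 127 ± 7.19 and 212 ± 28.7 CPM (0.74 ± 0.12, adjusted p = 0.161), and TP53AIP1 at 4.80 ± 0.339 and 1.83 ± 0.407 CPM (-1.39 ± 0.24, adjusted p = 0.257). With edgeR 0 of 15461 genes were called and 1042 had an unadjusted p below 0.05, of which 501 were higher and 541 lower. DESeq2 called 78, 37 higher and 41 lower, ID1, NNMT and TP53AIP1 among them. A single gene was called without CTR_LO replicate 2 and a single gene without CTR_HI replicate 2.

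All 33 G2 and M phase genes were negative in FMD_HI too, with a median of -0.634 (camera, adjusted p = 2.8e-15, adjusted p = 0.571 with an estimated correlation), but the libraries overlapped: the mean log2 CPM of the list was 5.31, 4.87 and 4.44 in CTR_HI and 4.2, 3.78 and 4.7 in FMD_HI. CDK1 stood at 31.1 ± 10.3 and 19.2 ± 5.25 CPM (-0.69 ± 0.26, adjusted p = 0.637). Fatty acid oxidation and ketone genes lay higher, with 25 of 31 positive, a median of 0.155 and 8 rising when adjusted over the list alone (adjusted p = 2.58e-05), and this list kept its call with an estimated correlation (adjusted p = 0.0382). CPT1A, which commits fatty acids to mitochondrial oxidation (chromosome 11, 68754620 to 68844277), stood at 29.8 ± 8.15 and 59.2 ± 16.5 CPM (0.99 ± 0.26, adjusted p = 0.457). ACADVL, the first dehydrogenase of that pathway for very long chains (chromosome 17, 7217125 to 7225266), stood at 187 ± 34.6 and 302 ± 43.7 CPM (0.69 ± 0.18, adjusted p = 0.431). No member of any list passed over all genes in this comparison, and in 8 of the 16 lists called the libraries of the 2 diets overlapped. Hypoxia genes had a median of 0.40 and no call when adjusted over the list alone (adjusted p = 9.94e-08, adjusted p = 0.571 with an estimated correlation), and their mean log2 CPM was 5.67, 6.45 and 5.65 in CTR_HI against 6.39, 6.36 and 6.58 in FMD_HI, so that CTR_HI replicate 2 lay among the FMD_HI libraries. ANGPTL4, an inhibitor of lipoprotein lipase, stood at 31.8 ± 24.4 and 119 ± 19.5 CPM (1.91 ± 0.60, adjusted p = 0.559). Of 34 lysosome and autophagy genes 30 were positive, 1 rose when adjusted over the list alone and the median was 0.186 (adjusted p = 3.81e-06, adjusted p = 0.204 with an estimated correlation). CTSD, the lysosomal protease cathepsin D (chromosome 11, 1752755 to 1763927), stood at 750 ± 64.5 and 1130 ± 68.7 CPM (0.59 ± 0.13, adjusted p = 0.342). Immediate early genes had a median of 0.187 and 2 rose when adjusted over the list alone (adjusted p = 3.59e-04, adjusted p = 0.571 with an estimated correlation), and antigen presentation genes a median of 0.158 with no call when adjusted over the list alone (adjusted p = 9.81e-05, adjusted p = 0.176 with an estimated correlation).

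Myeloid markers lay higher in FMD_HI as well, with a median of 0.745 and no call when adjusted over the list alone (adjusted p = 3.57e-05, adjusted p = 0.204 with an estimated correlation). SPI1 stood at 0.997 ± 0.318 CPM in CTR_HI and 2.67 ± 1.45 in FMD_HI (1.44 ± 0.41, adjusted p = 0.50). The 15 fibroblast markers lay lower with a median of -0.663 and no call when adjusted over the list alone (adjusted p = 0.0176, adjusted p = 0.571 with an estimated correlation), a call lost without CTR_HI replicate 3 at adjusted p = 0.247 and without FMD_HI replicate 3 at 0.0857. The remaining lists were each lost without a single library. Cholesterol-synthesis genes (median -0.159, 1 fell when adjusted over the list alone, adjusted p = 6.19e-04) had adjusted p = 0.111 without CTR_HI replicate 2, and NF-kB and inflammatory cytokine genes (median 0.151, none alone, adjusted p = 3.13e-04) had 0.226 without CTR_HI replicate 3. Glycolysis genes (median 0.138, none alone, adjusted p = 9.39e-05) had 0.111 without CTR_HI replicate 3 and 0.0857 without FMD_HI replicate 3. FOXO targets (median 0.134, none alone, adjusted p = 0.0151) had 0.235 without CTR_HI replicate 1 and 0.267 without FMD_HI replicate 2, and mammary basal markers (median -0.221, none alone, adjusted p = 0.0155) had 0.323 without CTR_HI replicate 1 and 0.0586 without FMD_HI replicate 1.

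TGF-beta targets (median 0.122, 1 rose and 1 fell when adjusted over the list alone, adjusted p = 0.0127) had adjusted p = 0.062 without CTR_HI replicate 3, 0.0693 without FMD_HI replicate 1 and 0.14 without FMD_HI replicate 2. G1 and S phase genes (median -0.165, none alone, adjusted p = 0.00613) had 0.812 without FMD_HI replicate 2, and without CTR_HI replicate 1 they pointed the other way with adjusted p = 0.616. Interferon response genes (median 0.0889, none alone, adjusted p = 0.0195) had 0.0881 without CTR_HI replicate 1, 0.757 without CTR_HI replicate 2, 0.0575 without FMD_HI replicate 2 and 0.311 without FMD_HI replicate 3. With an estimated correlation the adjusted p was 0.379 for the mammary basal markers, 0.571 for the cholesterol, glycolysis and NF-kB lists, 0.743 for FOXO targets, 0.766 for TGF-beta targets and 0.904 for the G1 and S phase and interferon lists.

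Genes that differed between diets in CD24-low cells were looked up in CD24-high cells. Of the 670 lower in FMD_LO, 584 (87.2%) also had a negative log2 fold change in FMD_HI, with a median of -0.178. Of the 1863 higher in FMD_LO, 1142 (61.3%) were positive in FMD_HI, with a median of 0.0602. ID1 and TP53AIP1 pointed the same way in both populations, and PTPRC stood at 2.28 ± 0.302 CPM in FMD_HI against 3.19 ± 1.31 in CTR_HI. These shares are not independent evidence, since CD24-low and CD24-high libraries of the same number went together within the fasting-mimicking diet.

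**Figure D4:**
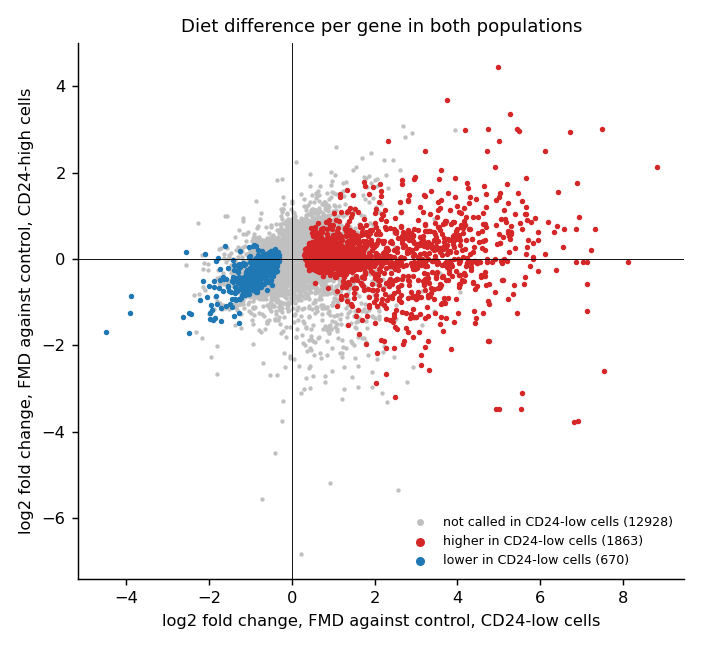
Log2 fold change between diets of each gene in CD24-low cells against that in CD24-high cells. Red points are the 1863 genes higher and blue points the 670 genes lower in CD24-low cells of the fasting-mimicking diet, and gray points are all others.

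Comparing CD24-high with CD24-low cells asked how the more differentiated and the stem-like sorted populations differ. Host reads were not separated in these comparisons, so neither higher nor lower values need be differences between tumour cells. Under the control diet no gene was called, which with 3 libraries against 3 does not show that none differed. The smallest unadjusted p in each direction were of AURKAPS1, a pseudogene, which stood at 1.28 ± 0.314 CPM in CTR_LO and 2.10 ± 0.107 in CTR_HI (0.72 ± 0.26), and LPAR6, a lysophosphatidic acid receptor (chromosome 13, 48389571 to 48444669), which stood at 27 ± 1.24 and 20.9 ± 2.64 CPM (-0.37 ± 0.13), both with adjusted p = 1. With edgeR 0 genes were called and 91 had an unadjusted p below 0.05, fewer than the 773 that chance alone gives on average, and DESeq2 called 0. With a block by number 0 were called and 518 had such a p, so the size of the shortfall depends on the fit. A pairing of the control libraries, which the main fit would ignore, was not excluded and could lower the number of small p. All 47 ribosomal protein genes were lower in CTR_HI, with a median of -0.149, no member passing over all genes or adjusted over the list alone (camera, adjusted p = 3.26e-13, adjusted p = 0.973 with an estimated correlation). RPS15A stood at 1030 ± 89.6 CPM in CTR_LO and 895 ± 108 in CTR_HI (-0.20 ± 0.12). In 6 further lists, again without a member that passed over all genes or adjusted over the list alone, the call was lost without single libraries. G2 and M phase genes (33 of 33 positive, median 0.154, adjusted p = 0.038) kept it in 7 of 12 such fits with adjusted p up to 0.693 without CTR_LO replicate 1, and G1 and S phase genes (29 of 30 positive, median 0.123, adjusted p = 0.035) in 8 of 12 with up to 0.578 without CTR_LO replicate 2. Without CTR_HI replicate 1 both cell cycle lists pointed the other way, with adjusted p of 0.313 and 0.102.

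Glycolysis genes (median 0.0696, adjusted p = 0.0428) kept their call in 5 of 12 fits and pointed the other way without CTR_HI replicate 2 at adjusted p = 0.883. Fatty acid synthesis genes (median 0.0892, adjusted p = 0.0463) kept it in 4 of 12 with adjusted p up to 0.568 without CTR_HI replicate 3. Skeletal muscle markers (median -0.319, adjusted p = 0.0463) kept it in 4 of 12 with up to 0.71 without CTR_HI replicate 1, and nerve and glia markers (median -0.745, adjusted p = 0.035) in 8 of 12 with up to 0.15 without CTR_HI replicate 2. With an estimated correlation the adjusted p of these 6 lists was 0.973, but 0.862 for skeletal muscle markers and 0.685 for nerve and glia markers. With every read counted whatever its strand, only the ribosomal list kept its call. With a block by number the ribosomal, glycolysis (adjusted p = 0.0463) and fatty acid synthesis (0.0465) lists kept theirs and heat shock genes gained one (0.0465). Both cell cycle lists and skeletal muscle markers (0.0545) and nerve and glia markers (0.167) lost theirs.

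Under the fasting-mimicking diet the populations differed widely, with most of the difference made of genes lower in CD24-high cells. This comparison used the same FMD_LO libraries as the diet comparison above, so host reads may account for part of these genes. By camera with its preset correlation, leukocyte, fibroblast, vessel and mesenchymal lists lay lower as groups in FMD_HI than in FMD_LO. None of the 16 lists called kept its call with an estimated correlation, where the smallest adjusted p was 0.366. EDN2, an endothelin peptide (chromosome 1, 41478775 to 41484683), was among the higher genes, at 22.1 ± 5.77 against 9.67 ± 0.649 CPM (1.19 ± 0.23, adjusted p = 0.00312). HDC, which makes histamine (chromosome 15, 50241947 to 50265726), stood at 267 ± 17.5 CPM in FMD_LO and 1.08 ± 1.37 in FMD_HI (-7.99 ± 1.38, adjusted p = 0.00365). AMER2 had 165 counts in FMD_LO and 0 in FMD_HI, at least 109-fold fewer, and KIT, the stem cell factor receptor of mast cells, had 126 and 0, at least 83.2-fold fewer. FPR2 had 411 counts against 2, a ratio of 407 with a counting interval of 112 to 3370. Of 15461 genes 2163 differed, 284 higher in FMD_HI with a median of 0.546 and 1879 lower with a median of -1.52. With libraries of the same number as a block, 4201 differed, 2147 of them shared. Counts of list members for this comparison come from the fit without the block and may miss members that the block would call. Without single libraries the higher genes numbered 158 (FMD_HI replicate 1), 68 (FMD_LO replicate 2) and 142 (FMD_HI replicate 2).

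Marker lists lay lower in FMD_HI by camera. Of 13 myeloid markers 5 fell, and 6 fell and 1 rose when adjusted over the list alone. The median was -1.67 (adjusted p = 0.00432, adjusted p = 0.366 with an estimated correlation). PTPRC stood at 51.3 ± 7.78 CPM in FMD_LO and 2.28 ± 0.302 in FMD_HI (-4.49 ± 0.27, adjusted p = 8e-07). Of 15 fibroblast markers 10 fell and 1 rose, and 11 fell and 1 rose when adjusted over the list alone. The median was -2.64 (adjusted p = 3.86e-06, adjusted p = 0.366 with an estimated correlation). Of 13 endothelial markers 5 fell, and 6 fell when adjusted over the list alone. The median was -0.97 (adjusted p = 0.015, adjusted p = 0.366 with an estimated correlation). TIE1, a receptor of vessel cells (chromosome 1, 43300982 to 43323108), stood at 19.3 ± 15.1 and 0.437 ± 0.182 CPM (-5.44 ± 1.02, adjusted p = 0.00515). Of 5 nerve and glia markers 3 fell, and 4 fell when adjusted over the list alone. The median was -2.96 (adjusted p = 0.0142, adjusted p = 0.366 with an estimated correlation). MBP, a myelin protein (chromosome 18, 76978833 to 77133708), stood at 1.36 ± 0.259 and 0.167 ± 0.12 CPM (-2.96 ± 0.57, adjusted p = 0.00284).

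Of 35 mesenchymal genes 17 fell, and 24 fell when adjusted over the list alone. The median was -1.15 (adjusted p = 1.01e-07, adjusted p = 0.449 with an estimated correlation). LOX stood at 150 ± 43.6 CPM in FMD_LO and 23.0 ± 3.86 in FMD_HI (-2.71 ± 0.29, adjusted p = 7.96e-05). COL1A1, the other chain of type I collagen (chromosome 17, 50184101 to 50201631), stood at 23700 ± 3450 and 8000 ± 932 CPM (-1.57 ± 0.21, adjusted p = 1.96e-04). Of 36 matrix genes 11 fell and 2 rose, and 16 fell and 3 rose when adjusted over the list alone. The median was -0.399 (adjusted p = 0.0205, adjusted p = 0.827 with an estimated correlation), with adjusted p = 0.113 without FMD_LO replicate 1 and 0.0789 without FMD_HI replicate 3. Among the 12 genes chosen from what is known of the study, which is no independent evidence, IGF1R fell to 86.1 ± 15.7 CPM (-1.06 ± 0.18, adjusted p = 0.00135) and CREB1 to 30.6 ± 2.67 CPM (-0.54 ± 0.11, adjusted p = 0.00485), and the same 2 fell when adjusted over the list alone (list median -0.0937, adjusted p = 0.516). Blocking by number also called CD44 (0.53 ± 0.18, adjusted p = 0.0775 without and 0.0116 with the block), KLF5 (0.58 ± 0.34, 0.311 and 0.00116) and CCND1 (0.42 ± 0.17, 0.134 and 0.0204).

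Of 30 epithelial genes 4 rose and 2 fell, and 7 rose and 2 fell when adjusted over the list alone. The median was 0.474 (adjusted p = 0.00876, adjusted p = 0.449 with an estimated correlation), with adjusted p = 0.0569 without FMD_HI replicate 3. Of 29 NF-kB and inflammatory cytokine genes 2 rose, and 2 rose when adjusted over the list alone. The median was 0.582 (adjusted p = 0.00432, adjusted p = 0.827 with an estimated correlation), and TNFAIP2, a TNF-induced gene (chromosome 14, 103121469 to 103137439), rose from 366 ± 12.2 to 609 ± 64.7 CPM (0.73 ± 0.15, adjusted p = 0.00494). Of 20 antigen presentation genes 1 rose and 1 fell, and 1 rose and 1 fell when adjusted over the list alone. The median was 0.277 (adjusted p = 0.00887, adjusted p = 0.366 with an estimated correlation). Of 39 interferon response genes 1 rose and 1 fell, and 1 fell when adjusted over the list alone. The median was 0.254 (adjusted p = 0.00731, adjusted p = 0.827 with an estimated correlation). In 6 lists higher in FMD_HI by camera, no member passed without the block, over all genes or adjusted over the list alone. Brackets hold the median, the adjusted p and the adjusted p with an estimated correlation. These were cholesterol-synthesis genes (0.299, 0.00665, 0.609), ribosomal protein genes (0.169, 0.00157, 0.827) and G1 and S phase genes (0.347, 0.00432, 0.827). The others were G2 and M phase genes (0.307, 0.0248, 0.827), MYC targets (0.197, 0.0239, 0.819) and oxidative phosphorylation genes (0.193, 0.0445, 0.827). The G2 and M list had adjusted p = 0.128 without FMD_LO replicate 1, 0.392 without FMD_LO replicate 2 and 0.637 without FMD_HI replicate 3. For MYC targets it was 0.0684 without FMD_HI replicate 1. For oxidative phosphorylation it was 0.329 without FMD_LO replicate 1, 0.547 without FMD_HI replicate 3 and 0.0601 with libraries thinned to equal depth.

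Averaged over both diets, CD24-high cells differed from CD24-low cells in 1164 genes, 45 higher with a median of 0.412 and 1119 lower with a median of -1.20. NCF1, a subunit of the phagocyte oxidase (chromosome 7, 74774011 to 74789315), was lower by this average (-3.21 ± 0.29, adjusted p = 4.71e-05), at 0.155 ± 0.0652 CPM in FMD_HI against 6.40 ± 1.55 in FMD_LO and 0.114 ± 0.0263 in CTR_HI against 0.251 ± 0.0574 in CTR_LO. DES, the muscle filament desmin (chromosome 2, 219418377 to 219426734), was lower too (-4.45 ± 0.69, adjusted p = 0.00228), at 0.0803 ± 0.0976 CPM against 9.08 ± 3.39 under the fasting-mimicking diet. The average mixed a comparison with 2163 calls and a comparison with 0, and host reads were not separated in it. The higher genes numbered 9 without CTR_LO replicate 1, 22 without CTR_HI replicate 1, 10 without CTR_LO replicate 2, 25 without CTR_HI replicate 2, 120 without CTR_LO replicate 3, 19 without FMD_HI replicate 1 and 6 without FMD_LO replicate 2. DESeq2 called 107 higher.

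The lists lower by this average were again markers and mesenchymal genes. Of 35 mesenchymal genes 13 fell, and 19 fell when adjusted over the list alone. The median was -0.664 (adjusted p = 1.47e-07, adjusted p = 0.578 with an estimated correlation). Of 15 fibroblast markers 6 fell and 1 rose, and 11 fell and 1 rose when adjusted over the list alone. The median was -1.41 (adjusted p = 3.28e-06, adjusted p = 0.429 with an estimated correlation). Of 13 myeloid markers 4 fell, and 5 fell when adjusted over the list alone. The median was -1.10 (adjusted p = 0.00447, adjusted p = 0.445 with an estimated correlation, 0.061 with a block by number). Of 13 endothelial markers 4 fell, and 6 fell when adjusted over the list alone. The median was -0.401 (adjusted p = 0.011, adjusted p = 0.429 with an estimated correlation). Of 8 skeletal muscle markers DES and ACTA1 fell, and 3 fell when adjusted over the list alone. The median was -0.588 (adjusted p = 0.0168, adjusted p = 0.429 with an estimated correlation, 0.0649 without CTR_HI replicate 1). Of 5 nerve and glia markers 3 fell, and 4 fell when adjusted over the list alone. The median was -2.01 (adjusted p = 0.00886, adjusted p = 0.429 with an estimated correlation, 0.0513 with a block by number).

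The lists higher by this average had few members that passed. NF-kB and inflammatory cytokine genes (1 rose, none alone, median 0.299, adjusted p = 0.00447) had adjusted p = 0.833 with an estimated correlation and 0.0658 without CTR_HI replicate 2. Epithelial genes (1 fell, 1 alone, median 0.215, adjusted p = 0.0308) had adjusted p = 0.727 with an estimated correlation, and kept their call in 4 of 12 fits without a library, with up to 0.165 without FMD_HI replicate 3 and 0.0554 with reads of either strand. Antigen presentation genes (1 fell, 1 alone, median 0.153, adjusted p = 0.024) had adjusted p = 0.445 with an estimated correlation, and 0.0658 without CTR_LO replicate 2, 0.0599 without CTR_HI replicate 2, 0.0527 without FMD_LO replicate 2 and 0.103 without FMD_HI replicate 3. Interferon response genes (1 fell, none alone, median 0.132, adjusted p = 0.0103) had adjusted p = 0.844 with an estimated correlation, and 0.129 without CTR_LO replicate 2, 0.17 without CTR_HI replicate 3 and 0.0517 without FMD_HI replicate 3. No cholesterol-synthesis gene (median 0.167, adjusted p = 0.00424, adjusted p = 0.604 with an estimated correlation) and no G1 and S phase gene (0.246, adjusted p = 9.16e-04, adjusted p = 0.844 with an estimated correlation, 0.0654 without CTR_HI replicate 1) passed over all genes or adjusted over the list alone. Neither did any G2 and M phase gene, of which 33 of 33 were positive (0.211, adjusted p = 0.00767, adjusted p = 0.877 with an estimated correlation), or any MYC target (0.11, adjusted p = 0.0308, adjusted p = 0.833 with an estimated correlation). The G2 and M list had adjusted p = 0.176 without CTR_HI replicate 1, 0.117 without FMD_LO replicate 2 and 0.262 without FMD_HI replicate 3. The MYC list kept its call in 7 of 12 such fits, with up to 0.148 without CTR_LO replicate 1.

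The interaction of diet and population asked whether the diet difference depended on the population, again without host reads separated from tumour reads. It was called in 638 of 15461 genes, 630 of them with a negative interaction, that is a diet change more positive in CD24-low than in CD24-high cells, and 8 with a positive one. PTPRC (-4.61 ± 0.37, adjusted p = 3.84e-05), SPI1 (-3.57 ± 0.56, adjusted p = 0.00443), THBS1 (-2.64 ± 0.30, adjusted p = 5.09e-04), LOX (-2.60 ± 0.40, adjusted p = 0.00384) and RRAGA (-1.19 ± 0.24, adjusted p = 0.0133) were negative. Mesenchymal, matrix, fibroblast and myeloid lists were negative by camera, and ribosomal protein genes were positive in 47 of 47 members. None of these lists kept its call with an estimated correlation, with adjusted p from 0.425 to 0.831. With a block by number within each diet, 1702 genes were called, 620 of them shared, and 4 lists were gained. They were immediate early genes (camera, adjusted p = 0.0266), protein kinase A regulators (0.0266), cholesterol synthesis (0.035) and MYC targets (0.0496). This block also pairs the control libraries, whose numbers were not taken to pair, so these blocked results rest in part on that pairing. Without a block, the number of genes called was 409 without CTR_LO replicate 3, 412 without FMD_LO replicate 1, 380 without FMD_LO replicate 2 and 403 without FMD_HI replicate 2, and 1127 with DESeq2.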

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

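The diet difference depended on the population in 638 genes by the interaction test, and each gene and list in this part is a difference between groups that this test called. Among genes with a positive interaction, SLC35F3 had 1.01 ± 0.26 and kept its call in 2 of 12 fits without a library, with adjusted p up to 0.129 without FMD_LO replicate 2. The value was 0.83 ± 0.19 for CLCA2 (5 of 12 fits, up to 0.0868 without FMD_LO replicate 2), 0.81 ± 0.20 for CARD16 (3 of 12, up to 0.102 without CTR_LO replicate 3) and 0.77 ± 0.19 for SLITRK6 (2 of 12, up to 0.114 without FMD_LO replicate 2). It was 0.64 ± 0.16 for FEZ1 (2 of 12, up to 0.126 without FMD_LO replicate 2) and 0.61 ± 0.15 for NET1 (3 of 12, up to 0.112 without FMD_LO replicate 2). The 8 positive genes numbered 15 without CTR_LO replicate 2, 2 without CTR_HI replicate 2, 0 without CTR_LO replicate 3, 1 without CTR_HI replicate 3, 4 without FMD_LO replicate 1, 4 without FMD_HI replicate 1, 0 without FMD_LO replicate 2, 1 without FMD_HI replicate 2, 16 without FMD_LO replicate 3 and 2 without FMD_HI replicate 3.

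The largest negative interactions were of genes with few counts outside FMD_LO, whose fitted values depend on the prior count. AMER2 had -8.67 ± 1.91, with 0 counts in FMD_HI and 3 in CTR_HI, and adjusted p = 1 without CTR_HI replicate 2, 0.0523 without CTR_LO replicate 3, 0.0538 without FMD_LO replicate 1 and 0.0518 without FMD_LO replicate 2. BEND4 had -8.34 ± 1.35, with 3 counts in FMD_HI, and adjusted p = 0.0636 without CTR_HI replicate 2. CLEC4E had -6.66 ± 1.63 and kept its call in 3 of 12 fits, with adjusted p up to 0.566 without CTR_HI replicate 2. MMP8 had -6.63 ± 1.40, with adjusted p = 0.213 without CTR_HI replicate 1 and 0.0504 without CTR_HI replicate 3. ALOX5 had -6.26 ± 1.13 (adjusted p = 0.00702). BATF had -6.19 ± 1.32, with adjusted p = 0.0532 without CTR_HI replicate 1 and 0.0886 without CTR_HI replicate 2.

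By camera, mesenchymal genes had a median interaction of -0.891 with 7 of 35 called and 14 adjusted over the list alone (adjusted p = 4.32e-07, adjusted p = 0.595 with an estimated correlation). Fibroblast markers had -2.23 with 5 of 15 called and 7 negative and 1 positive adjusted over the list alone (adjusted p = 1.16e-05, adjusted p = 0.425 with an estimated correlation), and myeloid markers -1.03 with 4 of 13 called and 5 adjusted over the list alone (adjusted p = 0.00377, adjusted p = 0.425 with an estimated correlation). Matrix genes had -0.454 with 6 of 36 called and 8 negative and 1 positive adjusted over the list alone (adjusted p = 0.00615, adjusted p = 0.743 with an estimated correlation). PI3K, AKT and mTOR components had -0.283 with 1 of 32 called and 5 adjusted over the list alone (adjusted p = 0.0293, adjusted p = 0.425 with an estimated correlation), and adjusted p of 0.069 without CTR_LO replicate 1, 0.0587 without CTR_LO replicate 2, 0.0709 without CTR_HI replicate 3 and 0.0955 without FMD_LO replicate 1. Epithelial genes had 0.49 with 1 of 30 called, negative, also adjusted over the list alone (adjusted p = 0.00997, adjusted p = 0.518 with an estimated correlation), and adjusted p = 0.0559 without FMD_HI replicate 3.

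Ribosomal protein genes had 0.345 (adjusted p = 1.68e-08, adjusted p = 0.831 with an estimated correlation), and in this list and the next 4 no member was called over all genes or adjusted over the list alone. Antigen presentation genes had 0.261 (adjusted p = 0.0144, adjusted p = 0.425 with an estimated correlation, 0.0559 without FMD_HI replicate 3). NF-kB and inflammatory cytokine genes had 0.519 (adjusted p = 0.014, adjusted p = 0.84 with an estimated correlation), with 0.0725 without CTR_LO replicate 2, 0.0865 without CTR_HI replicate 3 and 0.114 without FMD_LO replicate 3. Oxidative phosphorylation genes had 0.227 (adjusted p = 0.0117, adjusted p = 0.91 with an estimated correlation), with 0.285 without CTR_HI replicate 3, 0.0998 without FMD_LO replicate 1 and 0.21 without FMD_HI replicate 3. Interferon response genes had 0.272 (adjusted p = 0.0188, adjusted p = 0.91 with an estimated correlation), with 0.171 without CTR_HI replicate 2, 0.437 without CTR_LO replicate 3 and 0.0719 without FMD_HI replicate 3.

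Of the tests that follow, those of human leukocytes, of lower depth by thinning, of a diet difference shared by or equal in both populations and of chance splits were chosen after the result had been seen. The first pattern is the 1863 genes higher in FMD_LO. Mouse host cells could account for part of them, though they would have to have passed a gate on anti-human CD44 and CD24. Myeloid markers had a median of 2.12, and the 2 lymphoid markers measured (1.10) are too few to compare. The 62 genes of near-identical human and mouse sequence had a median of 0.393, above the 95th percentile of 0.0739 of matched random lists. Of these 62 genes 31 rose and 0 fell, where 1863 of all 15461 genes rose. In CD24-high cells their median was 0.00779. Human leukocytes are unlikely, since TYROBP, FCER1G, C1QA, C1QB, C1QC and CSF3R summed to 0.37 CPM in FMD_LO where PTPRC had 51.3. Counting depth is unlikely too, with 1846 genes higher after thinning, 1728 of them among the 1863, though thinning does not test a lower RNA input. A broad rise of stress genes is unlikely, with medians of 0.05 for immediate early and -0.0683 for heat shock genes. Yet the mean log2 CPM of the heat shock list was 7.68, 7.75 and 7.75 in FMD_LO against 7.29, 7.72 and 7.39 in CTR_LO. A rise of some of its members was therefore not excluded. An equal diet difference in both populations does not account for the whole pattern, with a negative interaction called in 617 of the 1863. Medians were 0.0602 in CD24-high and 1.20 in CD24-low cells. The genes were chosen for their rise in CD24-low cells, so a smaller median in CD24-high cells is partly built in. A smaller shared part (camera, p = 0.37 with an estimated correlation) was left undecided, and a diet effect on tumour cells of the CD24-low fraction was not separated from host reads. Alignment to human and mouse genomes together would part them, as would a sort that keeps the anti-human CD44 and CD24 gate and excludes cells bound by anti-mouse CD45 and stromal antibodies.

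The next pattern is the 670 genes lower in FMD_LO. Dilution by host reads may play a part and stays open: their median was -0.638 against -0.0315 for all genes, but they were chosen for being lower and scaling centres the median. Lower depth is unlikely, since 515 genes were called lower after thinning, 489 of them among the 670. A diet difference shared by both populations may account for part of them: in CD24-high cells the same genes lay below the others (p = 0.0121 with an estimated correlation, median -0.178), and whether an equal difference is the whole cause was left undecided, with a positive interaction called in 8 of the 670. That p does not allow for libraries of the same number going together within the fasting-mimicking diet.

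The last pattern is how many calls a split of the libraries gives by chance. For the average over both diets, 7 of 100 splits, the real one included, gave as many as the real 1164 calls, with 2007 the highest other, and for the interaction 9 of 100 gave as many as the real 638, with 2007 the highest other, so by these counts alone chance could not be excluded. All 7 and all 9 kept the libraries of FMD_LO and of FMD_HI together as groups, as 11 of the 100 splits did. Some of the 11 exchanged the labels of these 2 groups, which turns the average into the interaction and the reverse. The others of the 11, apart from the real split, regrouped only control libraries. The 7 and the 9 therefore say nothing about chance in the difference between FMD_LO and FMD_HI. Splits that parted these groups gave at most 1 and 2 calls. The other 4 comparisons have too few splits (10) to decide: CD24-high against CD24-low under the fasting-mimicking diet had 2163 against 0 for the highest other, the diets in CD24-low cells had 2533 against 0, and the populations under the control diet and the diets in CD24-high cells had 0 against 0. No biological explanation was tested for this pattern.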

How the results depend on the processing

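Of the named genes called in the main fit, none changed direction under any alternative, and none gained a call in the opposite direction. Changes of sign in genes called in neither fit were not counted. Over the fits without a library, named genes kept their side of the threshold in 4188 cases, lost a call in 263 and gained one in 37. Calls in CD24-low cells between diets ran from 1562 to 2795 over the 12 fits without a library, and the interaction from 380 to 767, with 1127 by DESeq2 and 1702 with a replicate block. The block gave 4201 genes between populations under the fasting-mimicking diet and 2549 over both diets. Between diets in CD24-high cells 1 gene was called without the count filter, 78 by DESeq2, 1 with a block and 0 to 1 without a library. The block also brought 2 lists under the fasting-mimicking diet below the threshold, PI3K, AKT and mTOR components (adjusted p 0.0669 to 0.0301) and protein kinase A regulators (0.0725 to 0.0451), and changed no other list there, and for the interaction it added 4 (0.0266 to 0.0496). Of 81 list calls an estimated correlation kept 1, and its counts were 0 in each contrast but 1 for the diets in CD24-high cells. Lists called between populations under the control diet were 1 with reads of either strand, 4 with a block (3 kept, 1 gained), 1 after thinning and 1 to 17 without a library (17 without CTR_HI replicate 3). For both diets they were 9 to 17 and for the interaction 8 to 18 without a library. In 4 cases a list without a library pointed the other way: under the control diet glycolysis (0.883 without CTR_HI replicate 2, range 1.08e-05 to 0.883), G1 and S (0.102 without CTR_HI replicate 1, range 1.7e-09 to 0.578) and G2 and M (0.313 without CTR_HI replicate 1, range 2.06e-09 to 0.693), and between diets in CD24-high cells G1 and S (0.616 without CTR_HI replicate 1, range 2.75e-07 to 0.812). RLE scaling moved the median of all genes in CD24-low cells between diets from -0.0315 to -0.0033 and the share of called genes that were higher from 73.5% to 78.7%. Fits without a library have fewer samples; for the other changes the cause was not tested.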

Other observations

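Markers of muscle, red blood cells and basal epithelium that belong to no list called between diets in CD24-low cells also differed in level. ACTA1, the actin of skeletal muscle, stood at 73.9 CPM in FMD_LO against 2.45 in CTR_LO, 1.12 in CTR_HI and 1.39 in FMD_HI, and DES at 9.08 against 0.567, 0.126 and 0.0803. Of 8 skeletal muscle markers 4 rose in FMD_LO against CTR_LO, 4 rose and 1 fell when adjusted over the list alone, and the list was not called (median 0.634, adjusted p = 0.276). HBB, the beta chain of haemoglobin, stood at 14.5 CPM in FMD_LO against 1.80, 1.87 and 1.91 in CTR_LO, CTR_HI and FMD_HI. The smooth muscle actin ACTG2 stood at 47.1 CPM against 3.74, 2.37 and 1.25. Keratins of basal epithelium stood lower: KRT5 at 1750 CPM in FMD_LO against 4350 in CTR_LO, 4200 in CTR_HI and 2880 in FMD_HI, and KRT17 at 3230 against 5990, 5950 and 5170. Of 15 mammary basal markers 6 fell and 3 rose, the same when adjusted over the list alone (median -0.323, adjusted p = 0.295).

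Lists of stemness were not called by camera between diets in CD24-low cells, though their mean log2 CPM was higher in each FMD_LO library than in each CTR_LO library. Such separation was common here: libraries overlapped in only 2 of the 17 lists called, and fibroblast, endothelial and myeloid markers were among those apart. Host reads were not separated, so it need not lie in tumour cells. Of 15 pluripotency and stemness factors 4 rose and 5 rose when adjusted over the list alone (median 0.268, adjusted p = 0.185), and of 22 breast cancer stem cell markers 5 rose and 1 fell, the same when adjusted over the list alone (median 0.104, adjusted p = 0.437). Targets of CREB had 4 of 25 rising, 4 when adjusted over the list alone, a median of 0.157 and adjusted p = 0.138, and glycolysis genes 2 of 23 rising and 1 falling, the same when adjusted over the list alone, a median of 0.236 and adjusted p = 0.118. Lymphoid and erythroid markers were not tested as lists, with 2 of 15 and 2 of 10 measured.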
